A study of Homo sapiens with 6 samples.

How the data were processed

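RNA was measured in 6 libraries of the human chronic myeloid leukaemia line K562, 3 from azacitidine-sensitive cells and 3 from azacitidine-resistant cells. Per the labels' protocols, the libraries were made from DNase-treated total RNA with a stranded kit after ribosomal RNA removal and sequenced in pairs on a NovaSeq instrument. Per the submitters' processing notes, the tools were Trimmomatic 0.39, HISAT2 2.2.1, featureCounts and Subread 2.0.3, with the genome build GRCh38. The annotation release, the strand setting of the counting, and whether reads or fragments were counted are not given in the sources used here. Overlapping and antisense genes, and near-identical copies such as histone, globin, HLA and GAGE genes, are therefore uncertain in the counts.

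The deposited values are raw counts per Ensembl gene, whole numbers whose totals differ between libraries. The table held 61487 gene IDs and no row without a gene. Symbols were found for 61369 IDs in a reference name table and positions for 58312 in GENCODE 29, also on GRCh38. The positions printed are from GENCODE 29, which may differ from the authors' annotation release.

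The labels call the libraries biological replicates without saying whether the cultures were kept apart, so p-values measure the spread between these libraries. Total counts ranged from 33007642 to 43006918 per library. A count of 0 in a library allows up to 0.0698 to 0.0909 CPM (3 counts of the total). For a gene with 0 counts in every library of a group, folds were computed against 3 counts over that group and are lower bounds. For 1 to 3 counts, the ratio is given with its exact 95% binomial interval. Both cover counting error only.

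The groups were compared with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 20891, scaled with TMM factors and tested with the robust quasi-likelihood test, two-sided. Genes at a Benjamini-Hochberg adjusted p below 0.05 are called higher or lower, and a second count also requires a log2 fold change of at least 1 in size. Every adjusted p of a gene is from this fit unless another tool is named. CPM values use the TMM-scaled totals and are given as mean ± SD over 3 libraries. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F, an approximation. H19 was also tested with an exact permutation test.

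The 27 gene lists were fixed before the data were examined, and 1033 of their 1035 entries matched a gene ID. Each list with at least 5 tested members, and each chromosome except Y, was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Benjamini-Hochberg adjustment was over lists or over chromosomes. The tests were repeated with a correlation estimated from the data, and for lists with fry. The members passing are counted over all genes tested and adjusted over the list alone.

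The genes named were set by a rule written before the data were examined. It took 17 fixed genes, the 10 highest and 10 lowest fold changes among called genes whose groups did not overlap, with a mean count of at least 100 in the higher group and no placeholder name, and up to 4 members per list with the smallest adjusted p. Leukocyte genes and genes of the deletion at 9p21 named in tests of explanations fall outside this rule.

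After the data were examined, protein-coding genes above a log2 CPM of 3 were placed in order along each chromosome in 302 windows of 30 neighbours. Each window's median log2 fold change was set against the family-wise 95% limit from 10000 shuffles of genes over positions. The shuffles treat genes as independent.

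The alternatives were DESeq2 1.42.0 size factors, upper quartile factors and library totals alone, no filter or at least 50 counts in 3 libraries, removal of mitochondrial genes, ribosomal RNA genes and the 10 most abundant features, a replicate block, each library left out in turn, DESeq2 and limma-voom, an adjusted p below 0.01, and glmTreat against 1.5-fold. Chosen after seeing the data were a comparison without both libraries numbered 3 and offsets for transcript length and GC content, from a smooth fit with a span of 0.3. These offsets left rank correlations of the library deviations with length of up to 0.182 (resistant replicate 1, 0.427 before). For the windows and for the libraries numbered 3, the same kind of trend was taken directly from the fold changes or from the deviations.

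The steps were tested on simulated counts drawn from the means and library sizes of these libraries, with 200 of the genes changed, in 3 simulations. Over 20565 tested genes in this comparison, edgeR recovered 87.4% of 4-fold, 43.8% of 2-fold and 3.98% of 1.5-fold changes. Of its calls, 11.2% were unchanged genes, above the nominal 5%. With only 200 genes changed, an adjusted p below 0.05 was harder to reach than in the real comparison. The recovery shares therefore do not carry over to it directly. This reason does not account for the share of unchanged genes, which may also exceed 5% among the genes called in the data. With 20891 genes, a shift of 0.4 (log2) of chromosome 15 was called in 3 of 3 simulations and no other chromosome was called. A shift of 0.8 was found in 30 of 30 windows with 0 false windows. Genes were drawn independently of each other, and for the windows no gene outside chromosome 15 was changed. False windows were therefore unlikely from the start, and these results do not measure errors among the correlated genes of the data. Most window shifts in the data were smaller than 0.8. Levels of sex-linked marker genes and of some genes the rule takes are not reported here.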

Results

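K562 is an established line from a patient with chronic myeloid leukaemia that carries the BCR-ABL1 fusion and can take on erythroid or megakaryocytic features. Azacitidine is a cytidine analogue that is incorporated into RNA and DNA and traps DNA methyltransferases. A resistant population was derived by exposing the line to rising drug concentrations over months. The 3 sensitive and 3 resistant libraries, labelled as biological replicates, were compared to ask how the resistant cells differ and where H19 stands. The p-values do not separate resistance from other changes that arose in the derived population. Total counts were 40616331, 34924828 and 43006918 in the sensitive and 33007642, 37991708 and 36669944 in the resistant libraries. Mitochondrial ribosomal RNA took between 12.8% and 16.2% of counts in the sensitive libraries and 17.8%, 16.8% and 8.54% in resistant replicates 1, 2 and 3. Small nucleolar RNA took 0.404%, 0.616% and 0.695% against 0.114%, 0.116% and 0.227%. The libraries numbered 3 stood apart from the other 2 of their group on the second principal component, which held 13.3% of the variance, while the first, with 79.3%, separated the groups.

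Several transcripts of the sensitive cells were nearly absent from resistant cells. PTPRC, which encodes the leukocyte phosphatase CD45, fell from 593 ± 80.4 to 0.245 ± 0.198 CPM (SD, n = 3 per group), a log2 fold change of −11.22 ± 0.43 (SE), and −12.12 without resistant replicate 3. The receptor phosphatase genes PTPRR and PTPRB, which lie side by side on chromosome 12 (PTPRR at 70638073 to 70920843, PTPRB at 70515866 to 70637440), fell from 43.1 ± 9.24 CPM to no counts and from 142 ± 22.8 to 0.132 ± 0.0725 CPM. PTPRR was at least 1637-fold lower, and the endocytic adaptor gene DAB2, from 22.3 CPM to no counts, at least 846-fold lower. MGST1, a microsomal glutathione transferase gene, fell from 28.4 ± 8.96 CPM to 1 count, in resistant replicate 2, a ratio of 3238 with a counting interval from 581 to 127940. Other genes with no counts in resistant cells were the nuclear receptor genes NR5A2 and PGR, at 5.48 ± 0.530 and 4.94 ± 2.85 CPM in sensitive cells, and PPDPFL, MPV17L and KCNT2, at 6.11 ± 1.79, 4.32 ± 0.212 and 4.16 ± 0.856 CPM. These were at least 158-fold (KCNT2) to 232-fold (PPDPFL) lower.

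In the opposite direction, S100A6, a calcium-binding protein gene, rose from 0.102 ± 0.0700 to 152 ± 24.6 CPM. The histone genes H4C6 and H3C11 had no counts in sensitive cells and rose to 28.7 ± 5.35 and 14.1 ± 3.11 CPM, at least 1067-fold and 525-fold higher. GRAMD1B, which encodes a cholesterol transporter, rose from 1 count, in sensitive replicate 1, to 9.50 ± 2.80 CPM, a ratio of 1051 with a counting interval from 188 to 41566. The neighbouring lncRNA genes LINC00507 and LINC02393 on chromosome 12 rose from 1 count (sensitive replicate 1) and 2 counts (sensitive replicate 3) to 4.59 ± 2.60 and 7.01 ± 0.168 CPM. Their ratios were 508 (interval 90.7 to 20087) and 391 (108 to 3232). The pseudogene KRT18P1 rose from 4 counts, all in sensitive replicate 1, to 11.8 ± 1.47 CPM. MUC3A, a mucin gene with near-identical copies, rose at least 177-fold from no counts, but its 388, 119 and 22 counts in the resistant libraries were uneven.

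Of 20891 genes tested with edgeR, 2054 were higher and 2741 lower in resistant cells at an adjusted p below 0.05, and 1277 and 1874 of these by at least 2-fold. Leaving out single libraries moved the counts by over 1.5 times: 1062 genes were higher without sensitive replicate 1, 1179 without sensitive replicate 2, 1362 without resistant replicate 1, 1051 (and 1677 lower) without resistant replicate 2, 3327 (2288 by at least 2-fold) without resistant replicate 3, and 4645 higher and 5021 lower (2548 higher by at least 2-fold) without both libraries numbered 3, an alternative chosen after the data were seen. Groups did not overlap for 40.1% of tested genes, where chance gives 10%. Higher genes made up 42.8% of calls with TMM and 58.9% (3041 higher, 2118 lower) with library totals alone, which moved the median log2 fold change of all genes from 0.03 to 0.20.

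**Figure D1:**
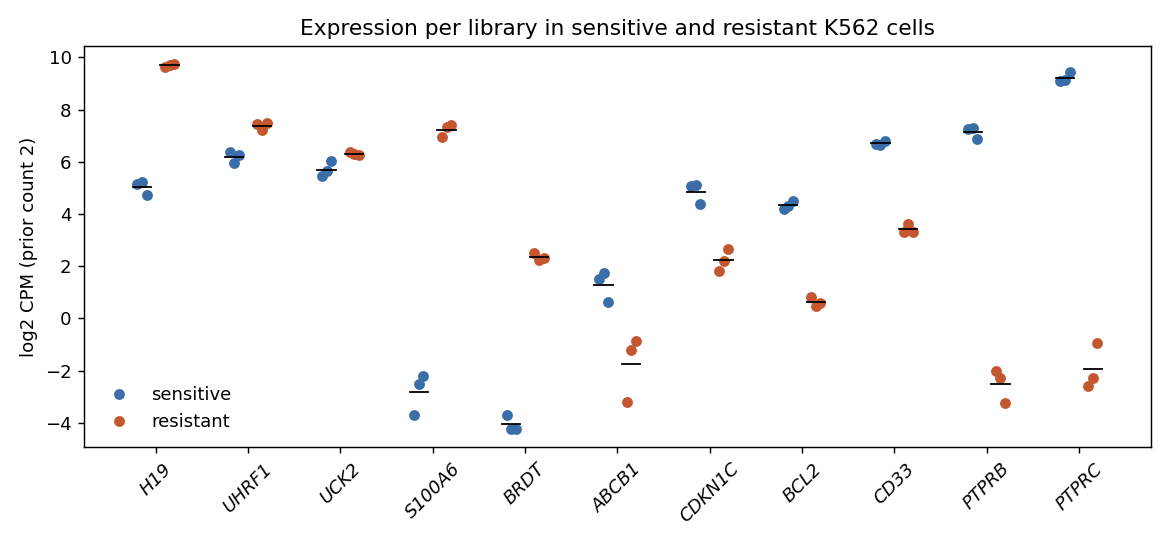
Expression of 11 named genes in each library, as log2 CPM with a prior count of 2, with sensitive libraries in blue, resistant libraries in orange and a black line at each group mean of 3 libraries. H19, S100A6 and BRDT were higher in every resistant library than in any sensitive one, and BCL2, CD33, PTPRB and PTPRC were lower.

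H19, the imprinted non-coding RNA named in the series title, rose from 33.1 ± 5.90 to 828 ± 32.4 CPM in resistant cells. It lies on chromosome 11 (1995176 to 2001470) and measured 35.3, 37.6 and 26.4 CPM in the sensitive and 792, 839 and 854 CPM in the resistant libraries. The log2 fold change was 4.65 ± 0.22 (SE), with an edgeR adjusted p of 1.37e-06, rank 21 of all genes by p. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Because the title states this direction, it is not an independent finding. Its neighbour IGF2, the growth factor gene of the same imprinted domain, had 0 counts in sensitive and 2 in resistant libraries.

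Most other tested members of the fixed list of imprinted genes at 11p15 fell. Membership of a list does not show that a gene is imprinted in these cells. Of 6 tested members, H19 rose and 4 fell, the same numbers when adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.457). Its median log2 fold change was −1.46 and its mean −0.45, camera gave the direction down and fry, a test of the list alone, up. Sensitive replicate 3 also lay low, with a list median relative to the sensitive mean of −0.68 against 0.34 and 0.29 in sensitive replicates 1 and 2, and −1.33, −1.18 and −1.31 in the resistant libraries. CDKN1C, which encodes the cell cycle inhibitor p57, fell from 29.5 ± 7.78 to 4.78 ± 1.43 CPM. TSPAN32 fell by 1.47 ± 0.26 on the log2 scale (SE) and PHLDA2 from 1.64 ± 0.866 to 0.428 ± 0.159 CPM, the latter call being lost without sensitive replicate 1 (adjusted p = 0.122), sensitive replicate 2 (0.0961), resistant replicate 1 (0.0694) or resistant replicate 2 (0.0620). Among 28 imprinted genes elsewhere, 5 rose and 6 fell, also when adjusted over the list alone (adjusted p = 0.872). PLAGL1, a zinc finger regulator, fell 5.79-fold, SNHG14, the long transcript of the Prader-Willi region, fell 10.4-fold, and ZDBF2 rose 4.73-fold. SNRPN, beside SNHG14 on chromosome 15, fell from 179 counts to 1, in resistant replicate 3, a ratio of 183 with a counting interval from 32.4 to 7269.

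Granulocyte and monocyte genes were lower as a set with camera (adjusted p = 7.60e-07), but not with an estimated correlation (adjusted p = 0.264). Of 26 tested, 0 rose, 15 fell and 11 did not pass (17 fell when adjusted over the list alone), with a median log2 fold change of −1.83. CD33, a myeloid surface receptor, fell from 105 ± 6.34 to 10.6 ± 1.26 CPM. The Fc receptor genes FCGR2A and FCGR1A fell from 273 ± 37.1 to 27.8 ± 3.91 and from 7.01 ± 2.10 to 0.562 ± 0.147 CPM, and lysozyme (LYZ) from 53.6 ± 21.9 to 5.65 ± 1.01 CPM. No list call held with an estimated correlation, where 3 of 27 lists had an unadjusted p below 0.05.

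Megakaryocyte genes were also lower with camera (adjusted p = 8.21e-04), but not with an estimated correlation (adjusted p = 0.412). None of the 21 tested rose, 10 fell and 11 did not pass (11 fell when adjusted over the list alone), with a median of −0.85. F2RL3, the thrombin receptor PAR4, fell from 41.5 ± 3.53 to 5.64 ± 0.501 CPM, FERMT3, an integrin activator, from 135 ± 2.34 to 57.2 ± 2.40 CPM, and the proteoglycan gene SRGN from 115 ± 3.91 to 49.4 ± 13.2 CPM. The transcription factor gene MEIS1 fell 2.65-fold.

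Erythroid genes showed no common direction. Of 53 tested, 6 rose, 6 fell and 41 did not pass (6 and 7 when adjusted over the list alone), with a median of 0.07 and a camera adjusted p of 0.942. The list's median relative to the sensitive mean was −0.28, −0.19 and 0.42 in resistant replicates 1, 2 and 3, so the resistant libraries differed in sign. ANK1, the red cell ankyrin, rose from 138 ± 18.1 to 385 ± 50.9 CPM and HBA2, an alpha globin gene with a near-identical copy, had a log2 fold change of 2.57 ± 0.45 (SE). XK, a red cell membrane transporter gene, fell from 108 ± 8.08 to 35.5 ± 8.60 CPM, and SELENBP1 from 29.6 ± 7.86 to 9.18 ± 0.142 CPM.

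Of the fixed cancer-testis and germline genes, more rose than fell, and the list was higher with camera (adjusted p = 6.18e-05), but not with an estimated correlation (adjusted p = 0.412). Of 50 tested, 23 rose, 4 fell and 23 did not pass (25 and 4 when adjusted over the list alone), with a median of 1.12, also with the 2 members at 0 counts in a group set to their bounds. TEX14, a protein of germ cell bridges, rose from 0.900 ± 0.233 to 33.5 ± 2.90 CPM, TDRD12, of the piRNA pathway, from 0.102 ± 0.0769 to 17.6 ± 2.37 CPM, and the testis bromodomain gene BRDT from 1 count, in sensitive replicate 1, to 5.05 ± 0.519 CPM, a ratio of 561 with a counting interval from 100.4 to 22212. GAGE2A, from a family of near-identical X-linked genes, rose from 0.0686 ± 0.0479 to 5.18 ± 0.872 CPM. The log2 fold change of TDRD12 was 7.42, and 8.01 without sensitive replicate 2, and that of GAGE2A 6.12, and 6.80 without sensitive replicate 1.

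The replication-dependent histone list was higher with camera (adjusted p = 0.0385), but not with an estimated correlation (adjusted p = 0.924). Of 44 tested, 11 rose, 0 fell and 33 did not pass, the same when adjusted over the list alone. H2BC14 rose by 5.77 ± 0.28 and H3C3 by 6.25 ± 0.34 on the log2 scale (SE), and H1-1 from 0.307 ± 0.152 to 11.9 ± 1.57 CPM. The list's mean was 1.20 and its median 0.06, which stayed at 0.06 with H3C11 at its bound. The camera call was lost without sensitive replicate 1 (0.188), sensitive replicate 2 (0.206), resistant replicate 2 (0.0605) or resistant replicate 3 (0.368), where the median was between −0.07 and −0.03. It was also lost with at least 50 counts (0.0731), the replicate block (0.107) and fry (0.0753). This list was also higher in the libraries numbered 3 than in the mean of the other 2, by 0.69 in sensitive and 0.32 in resistant cells.

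Genes of the amino acid and unfolded protein stress responses were lower as a set with camera (adjusted p = 4.26e-04), but not with an estimated correlation (adjusted p = 0.880) or fry (0.0753). Of 37 tested, 1 rose, 17 fell and 19 did not pass (1 and 18 when adjusted over the list alone), with a median of −0.73. DDIT3, the stress transcription factor CHOP, fell from 105 ± 13.9 to 34.3 ± 6.28 CPM, HERPUD1, of endoplasmic reticulum degradation, from 82.2 ± 11.4 to 31.4 ± 4.03 CPM, the secreted glycoprotein gene STC2 from 16.6 ± 0.553 to 5.32 ± 2.38 CPM, and the mitochondrial folate enzyme gene ALDH1L2 from 63.0 ± 16.6 to 27.7 ± 3.97 CPM. The list's median relative to the sensitive mean was −0.86, −0.80 and −0.39 in resistant replicates 1, 2 and 3, and −0.22 in sensitive replicate 3.

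Apoptosis regulators were lower as a set with camera (adjusted p = 0.00169), but not with an estimated correlation (adjusted p = 0.805). Of 37 tested, 1 rose, 15 fell and 21 did not pass (1 and 16 when adjusted over the list alone), with a median of −0.52. BCL2, which blocks apoptosis, fell from 20.2 ± 2.15 to 1.49 ± 0.182 CPM. The death receptor genes TNFRSF10B and TNFRSF10A fell from 106 ± 27.7 to 32.5 ± 2.42 and from 51.1 ± 2.45 to 24.4 ± 1.29 CPM, and the gene of their ligand TRAIL, TNFSF10, fell by 4.18 ± 0.56 on the log2 scale (SE). The list's median relative to the sensitive mean was −0.75, −0.50 and −0.21 in resistant replicates 1, 2 and 3.

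**Figure D2:**
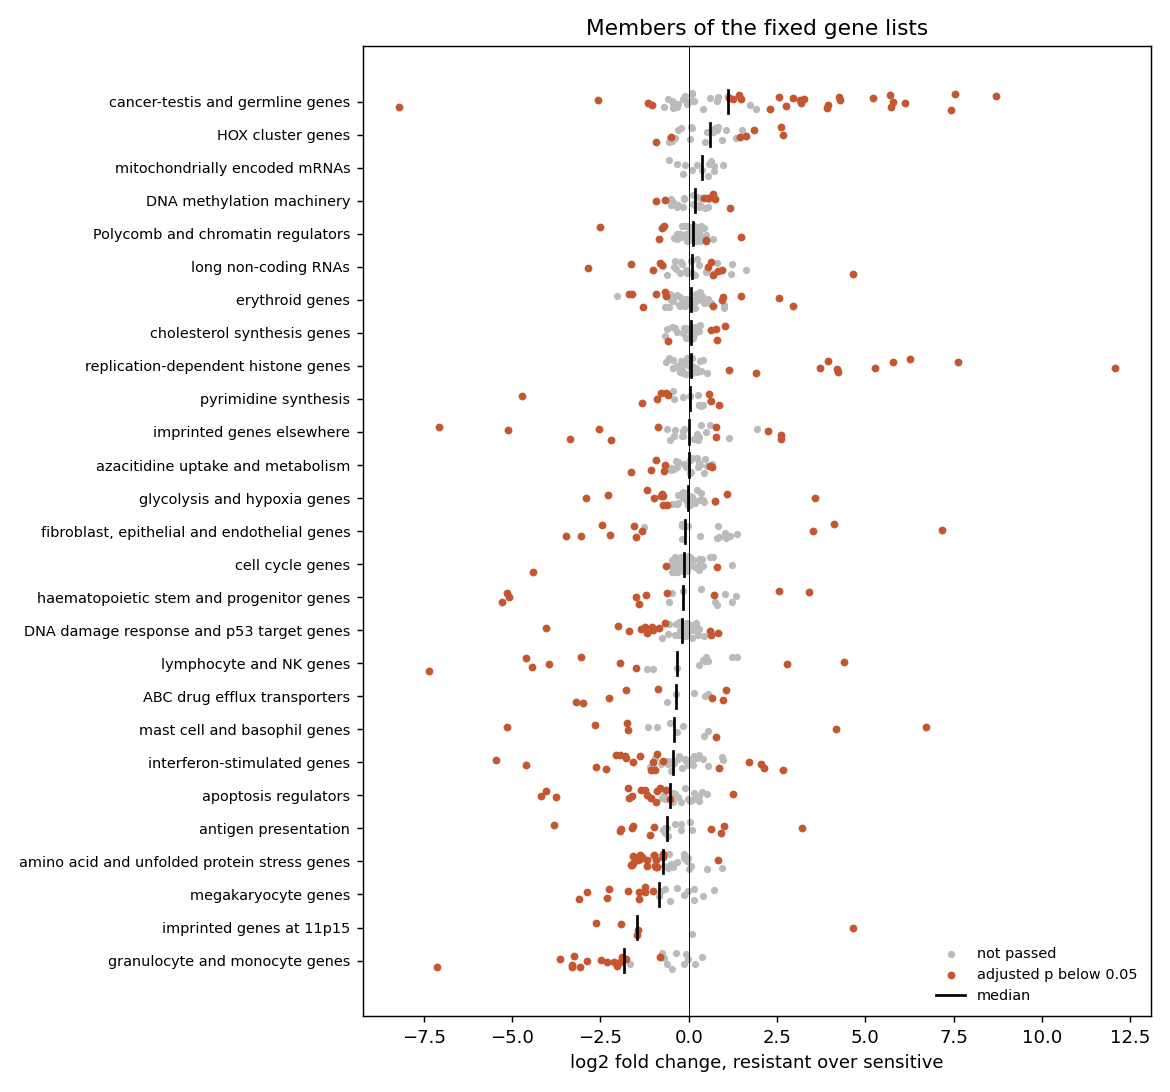
Log2 fold change (resistant over sensitive) of each tested member of the 27 gene lists, with genes at an adjusted p below 0.05 in orange, others in grey and a black line at each list's median. Granulocyte and monocyte genes had a median of −1.83 and cancer-testis and germline genes a median of 1.12, while the histone genes that rose lay far from their list's median of 0.06.

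Genes that take up and metabolise azacitidine showed no common direction. Of 28 tested, 2 rose, 5 fell and 21 did not pass, also when adjusted over the list alone, with a median of −0.00 and a camera adjusted p of 0.742. UCK2, the uridine-cytidine kinase that phosphorylates the drug, rose from 52.8 ± 10.9 to 79.6 ± 2.24 CPM (edgeR adjusted p = 0.0310), a call lost without sensitive replicate 1 (0.164), sensitive replicate 2 (0.143), resistant replicate 1 (0.0762) or resistant replicate 2 (0.122). UCKL1, a related kinase gene, rose 1.58-fold, a call also lost without sensitive replicate 1 (0.107), sensitive replicate 2 (0.112) or resistant replicate 2 (0.0863). The deaminase gene DCTD fell from 95.5 ± 8.46 to 59.3 ± 5.82 CPM (0.0514 without resistant replicate 2), the mitochondrial nucleotidase gene NT5M from 27.3 ± 7.97 to 8.81 ± 0.599 CPM, and NME3 from 15.3 ± 2.07 to 8.04 ± 1.60 CPM (0.0545 without sensitive replicate 2). The remaining fixed genes did not pass. The log2 fold change was −0.05 for UCK1, −0.51 for DCK, 0.04 for the transporter gene SLC29A1, 0.51 for SLC29A2, −0.35 and −0.41 for the ribonucleotide reductase genes RRM1 and RRM2, and 0.26 for SAMHD1, with adjusted p from 0.109 for DCK to 0.874 for SLC29A1. Without resistant replicate 3, DCK, which phosphorylates decitabine, was lower (−0.79, adjusted p = 0.00774), SLC29A2 higher (0.69, 0.0191) and RRM1 lower (−0.62, 0.0234). Without both libraries numbered 3, RRM2 was lower as well (−0.63, 8.93e-04). The cytidine deaminase gene CDA had 2 counts in sensitive and 0 in resistant libraries.

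Of 19 pyrimidine synthesis genes, 3 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.742, with a median of 0.04 and a mean of −0.30). CTPS1, which makes CTP from UTP, rose from 40.7 ± 7.44 to 74.3 ± 11.6 CPM. The folate enzyme genes SHMT2 and MTHFD2 fell from 378 ± 22.1 to 202 ± 52.4 and from 570 ± 34.4 to 228 ± 117 CPM, both calls being lost without resistant replicate 2 (adjusted p = 0.0905 and 0.0840). UPP2, a uridine phosphorylase gene, fell from 60 counts to 2, both in resistant replicate 3, a ratio of 30.7 with a counting interval from 8.13 to 259.

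Among 29 DNA methylation genes, 5 rose and 2 fell (7 and 3 when adjusted over the list alone), with a camera adjusted p of 0.457. UHRF1, which brings DNMT1 to hemimethylated DNA, rose from 73.9 ± 10.3 to 166 ± 16.9 CPM (log2 fold change 1.17 ± 0.17 SE, edgeR adjusted p = 9.20e-04), and ZBTB38 fell from 37.5 ± 4.38 to 19.6 ± 1.33 CPM. The DNA methyltransferase genes and TET2, a methylcytosine dioxygenase gene, did not pass. DNMT1 measured 224 ± 5.77 and 244 ± 15.9 CPM, DNMT3A 46.2 ± 6.36 and 36.4 ± 8.10 CPM, DNMT3B 57.3 ± 5.31 and 65.0 ± 2.57 CPM, and TET2 72.0 ± 11.8 and 65.1 ± 7.15 CPM in sensitive and resistant cells. With length and GC offsets DNMT3A was lower (−0.55, adjusted p = 0.00895).

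Drug efflux transporter genes moved both ways, 3 of 13 up and 5 down, also when adjusted over the list alone (camera adjusted p = 0.676). ABCB1, the P-glycoprotein gene, fell from 2.51 ± 0.924 to 0.310 ± 0.229 CPM, ABCG2 from 3.63 ± 0.819 to 0.397 ± 0.345 CPM and ABCC4 from 167 ± 18.7 to 91.8 ± 4.72 CPM. The log2 fold change of ABCG2 was −3.20, and −4.11 without resistant replicate 1. ABCC5, a nucleotide analogue exporter gene, rose 2.09-fold.

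Of 50 interferon-stimulated genes, 5 rose, 15 fell and 30 did not pass (6 rose and 17 fell when adjusted over the list alone), and the list was not called (camera adjusted p = 0.0714). It was called lower without sensitive replicate 1 (0.0306), sensitive replicate 3 (0.0185) or both libraries numbered 3 (0.0422), with library totals alone (0.0312), without a filter (0.0261) and with length and GC offsets (0.0275). IFITM1 fell from 159 ± 17.4 to 53.2 ± 14.3 CPM, UBE2L6 from 27.7 ± 11.2 to 6.67 ± 0.273 CPM, GBP2 from 7.15 ± 2.66 to 0.289 ± 0.116 CPM and IFIT3 from 5.66 ± 0.856 to 0.921 ± 0.282 CPM. Of 21 antigen presentation genes, 4 rose and 7 fell (4 and 8 when adjusted over the list alone), with a camera adjusted p of 0.177. HLA-E fell from 142 ± 10.2 to 37.1 ± 6.16 CPM.

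Genes of chromosomes 7, 15 and 20 were higher as sets with camera, but not with an estimated correlation (adjusted p = 0.0789, 0.0795 and 0.0789). The median log2 fold change was 0.37 over 1040 genes of chromosome 7, 0.41 over 708 genes of chromosome 15 and 0.23 over 477 genes of chromosome 20, with camera adjusted p of 1.51e-04, 3.11e-04 and 0.0290. With an estimated correlation no chromosome passed (7 at an unadjusted p below 0.05). The call for chromosome 20 was lost without sensitive replicate 1 (0.0562), resistant replicate 3 (0.148) or both libraries numbered 3 (0.169) and without a filter (0.165), and chromosome 4 was called lower without resistant replicate 2 (0.0490).

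Within chromosomes, 18 of 302 windows of neighbouring genes lay past the family-wise limit of 0.44, 14 higher and 4 lower, in 9 segments. The largest shift was on chromosome 1 from 103525691 to 116667755, where 60 genes had a median of 0.88 relative to all window genes. The segment on chromosome 15 from 65234460 to 101724604 held 136 genes with a median of 0.59, and that on chromosome 20 from 44910062 to 64287821 held 92 genes with a median of 0.63. The windows before these segments had medians from −0.08 to 0.15 on chromosome 15 and from −0.04 to 0.17 on chromosome 20. On chromosome 7, segments at 549197 to 5926550 and at 128790757 to 158956747 had medians of 0.47 and 0.49. The windows between these segments were also higher, with medians from 0.12 to 0.44, so the segments have no sharp edge there. Lower segments lay on chromosome 2 (217730 to 11827409, 26190635 to 27988087 and 38751534 to 47663146), with medians of −0.50, −0.53 and −0.51, and on chromosome 6 (125119049 to 138793319), with a median of −0.50. The windows between the chromosome 2 segments had medians of −0.397 and −0.404, just inside the limit. The limit thus cuts a longer lower stretch of chromosome 2 into separate segments.

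**Figure D3:**
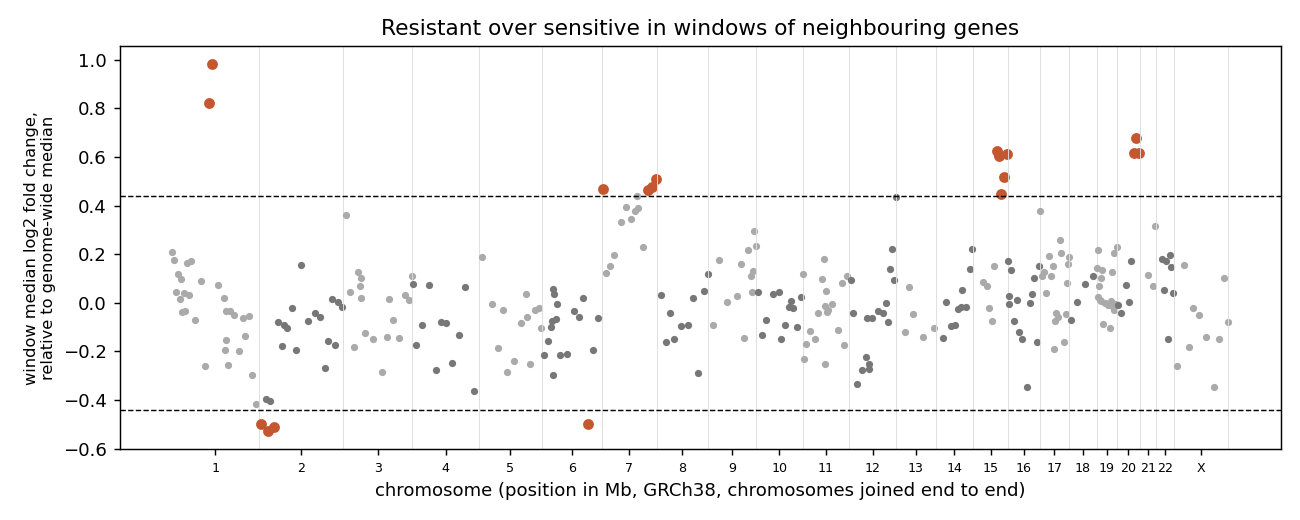
Median log2 fold change (resistant over sensitive, relative to the median of all window genes) in windows of 30 neighbouring protein-coding genes along chromosomes 1 to 22 and X, with dashed lines at the family-wise limits of ± 0.44 and windows past them in orange. The 18 windows past the limits gather on chromosomes 1, 2, 6, 7, 15 and 20.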

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

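H19 stayed higher and past the threshold under every alternative run for it, with a log2 fold change from 4.47 without both libraries numbered 3 to 4.80 with library totals alone, and from 4.50 to 4.72 when single libraries were left out. The comparison without both libraries numbered 3 and the length and GC offsets were chosen after the data were seen. Leaving out single libraries gave 1051 to 3327 genes higher and 1677 to 3718 lower, and 857 to 2288 and 1478 to 2223 by at least 2-fold. Without both libraries numbered 3, there were 4645 higher and 5021 lower genes, with 2548 and 2569 by at least 2-fold, and 4742 of the 4795 genes called with all libraries were among them. The adjusted p below 0.01 gave 938 higher and 1586 lower genes (746 and 1343 by at least 2-fold) and glmTreat 840 and 1429 (830 and 1419), both stricter by construction. DESeq2 gave 2429 and 3082 genes, limma-voom 1932 and 2692, and length and GC offsets 2792 and 2547, with a median log2 fold change of all genes of 0.14. Genes shared between the main calls and any alternative had the same direction in each.

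The labels do not say that a number marks a shared batch. The deviations of same-numbered libraries correlated across all 20891 tested genes at 0.202, 0.0850 and 0.299 for numbers 1, 2 and 3, so not every pair was above 0.1, and sensitive replicate 2 correlated best with resistant replicate 1 (0.230). With replicate number as a block, 2859 genes were higher and 3582 lower, 1 list was higher (2 without the block) and the other list and chromosome calls held.

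Of gene lists, 2 were higher and 4 lower. With an estimated correlation 0 were higher and 0 lower, and 0 chromosomes were higher (3 with the preset one). The filter of at least 50 counts left 1 list higher. Leaving out single libraries gave 1 to 2 lists higher and 4 to 6 lower, and 2 to 3 chromosomes higher and 0 to 1 lower. The cause of these changes was not tested. The 5 called lists other than histones were lost only with the estimated correlation, and for the stress list also with fry. When single libraries were left out, their adjusted p was at most 0.0153 (apoptosis regulators). H19 and 99 others of the 118 named genes called kept their call under each of the 17 alternatives run for single genes. This holds as far as they were tested there, and none of the 118 changed sign. The highest number of losses under 1 alternative came without resistant replicate 2 (16 genes). In simulations with 200 genes changed, 2-fold changes were recovered in 43.8% of cases (20565 genes). The threshold was harder to reach there, so this share does not measure how many such changes were missed in the data. Changes of this size that did not pass cannot be read as absent.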

Other observations

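Further fixed lists held large changes in single genes, and camera called none of these lists with all 6 libraries and the low-count filter. With fry, the lymphocyte and NK list was lower (adjusted p = 0.0385) and the HOX list higher (0.0385). The receptor tyrosine kinase gene KIT fell from 121 ± 13.4 to 3.45 ± 1.76 CPM and the adhesion receptor gene CD44 from 85.4 ± 4.93 to 2.51 ± 1.12 CPM. In the stem and progenitor list, 3 of 19 genes rose and 7 fell (6 and 8 adjusted over the list alone). In the mast cell list 3 of 14 rose and 4 fell, also when adjusted over the list alone, with FCER1A rising by 6.71 on the log2 scale (6.08 without sensitive replicate 1). Of 19 lymphocyte and NK genes, 2 rose and 7 fell (3 and 8 adjusted over the list alone), with a camera adjusted p of 0.333. CD3D fell from 47.3 ± 41.8 to 1.95 ± 0.396 CPM, a log2 fold change of −4.60, and −3.59 without sensitive replicate 3. Of 24 fibroblast, epithelial and endothelial genes, 3 rose and 7 fell, also when adjusted over the list alone (median −0.10, mean 0.19), with fibronectin (FN1) rising from 33.5 ± 13.9 to 383 ± 177 CPM and E-cadherin (CDH1) from 0.0460 ± 0.0190 to 6.88 ± 3.28 CPM. Of 26 HOX genes, 5 rose and 2 fell, with HOXC10 rising from 0.479 ± 0.210 to 2.92 ± 0.262 CPM (6 and 3 adjusted over the list alone). The HOX list had a camera adjusted p of 0.0714, 0.00516 without the low-count filter, 0.0479 without sensitive replicate 1 and 0.0413 without sensitive replicate 2.

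Of 56 cell cycle genes, 1 rose and 2 fell (0 and 1 adjusted over the list alone), and cyclin D1 (CCND1) fell from 35.2 ± 4.48 to 1.67 ± 0.606 CPM. Of 45 DNA damage and p53 target genes, 3 rose and 10 fell, also when adjusted over the list alone, with GADD45B falling 3.99-fold. Without resistant replicate 3, the cell cycle list (camera adjusted p = 0.0255, 0.457 with all libraries) and the DNA damage list (0.0218, 0.146 with all libraries) were called lower, the latter also without both libraries numbered 3 (0.00623). Of 36 glycolysis and hypoxia genes, 3 rose and 9 fell (4 and 9 adjusted over the list alone), and the glucose transporter gene SLC2A3 fell from 389 ± 7.19 to 79.6 ± 8.86 CPM. Of 27 cholesterol synthesis genes, 4 rose and 1 fell (4 and 3 adjusted over the list alone), with LSS rising 2.03-fold. Of 44 Polycomb and chromatin regulators, 3 rose and 4 fell (0 and 3 adjusted over the list alone), with HDAC9 falling from 4.80 ± 0.327 to 0.835 ± 0.211 CPM. Of 33 long non-coding RNAs, 6 rose and 5 fell, also when adjusted over the list alone, with CRNDE falling 2.02-fold beside the rise of H19. None of 13 mitochondrial mRNAs passed with edgeR, and without resistant replicate 3 MT-ATP6 (adjusted p = 0.00227) and MT-CO2 (0.00532) were higher. Their median log2 fold change was 0.37 while camera gave the direction down. Their median in resistant replicate 3 lay 1.71 (log2) below the mean of the other 2 resistant libraries. At 5 CPM or more in the higher group and under 5% of that level in the other, 103 genes were lost and 55 gained in resistant cells.

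The tests below were chosen after the results were seen, except the MTAP level and the window counts of other splits. The loss of PTPRC, PTPRR, DAB2 and other transcripts could come from leukocyte RNA in the sensitive cultures. Against this, 8 other abundant leukocyte transcripts had a median of 2.49 CPM there, with PTPRC at 593 CPM and the T cell receptor gene TRAC at 0.0163 CPM. The resistant libraries might also be from a cell line other than K562, but MTAP, which lies in the 9p21 deletion of K562, had 0 counts in every library of both groups, as had CDKN2A and CDKN2B. That test does not separate a cell line that shares this deletion. Regulation in the resistant cells and selection of a rare subclone of K562 both stay open and untested.

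Neighbouring genes shifted together on chromosomes 1, 2, 6, 7, 15 and 20. Bias that follows a smooth trend on transcript length and GC content is argued against as the whole cause, since 14 of the 18 windows stayed past the limit after correction. The segments at 549197 to 5926550 on chromosome 7 and 38751534 to 47663146 on chromosome 2 did not stay past it. Their medians after correction were 0.36 and −0.40, inside the corrected limit of 0.42. Copy number gains and losses in the selected cells are a candidate explanation, for which no DNA was analysed here. With limits from 1000 shuffles, the real split of the 6 libraries gave 17 windows and the highest other split also 17 (2 of 10 splits), too few splits for a share under 0.05. The largest window median was 0.98 in size in the real split and at most 0.40 in the others. Because the other splits put libraries of both groups on each side, they keep part of the group difference. Neither their window counts nor their medians show what chance alone would give.

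The libraries numbered 3 differed from the other libraries of their group in part in the same direction, with a correlation of their deviations of 0.391 across the 9594 genes above a log2 CPM of 3 that have a length and GC content. Other differences ran in opposite directions, as for the stress list (median lower by 0.32 in the sensitive and higher by 0.38 in the resistant library numbered 3), and on the third principal component they lay at −17.9 and 14.4. Length and GC bias may be part of the shared difference, since the correlation fell to 0.282 once a smooth trend on length and GC was taken from each library's deviations. Whether such bias explains the rest cannot be told from this fit. It left no library with a rank correlation with length above 0.0299 in size, but it removes its own trend by construction. Bias that this trend does not capture would remain. A batch shared by these 2 libraries stays open because the labels give none, and no biological explanation was tested.

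Splits of the 6 libraries into 3 and 3, the real one included, number 10, so no share under 0.05 can be reached. Every other split puts sensitive and resistant libraries on both sides. The group difference then widens the spread within each side, which makes gene calls unlikely from the start. Part of the group difference also stays between the sides and can move lists and chromosomes. For both reasons, the counts from the other splits do not show what chance alone would give. With edgeR, the real split called 4795 genes and 3151 by at least 2-fold, and the highest other split 0 and 0 (1 of 10 splits for each), with 7503 genes at an unadjusted p below 0.05 in the real split and up to 1485 in the others. For gene lists the real split called 6 and the highest other 11, with 7 of 10 splits calling at least 6. For chromosomes the real split called 3 and the highest other 6, with 2 of 10 splits calling at least 3.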
